A study of Solanum lycopersicum with 40 samples.

How the data were processed

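Transcript levels were measured on 40 Affymetrix tomato arrays, each hybridised with biotin-labelled RNA of 1 sample. The samples came from 3 tissues of 4 genotypes: wild type, a vector control and the transgenic lines N6 and N7. Each genotype had 4 arrays in ripe fruit, 3 in leaves and 3 in root tips. Groups and replicate numbers were taken from the sample titles. Titles of the fruit samples call the replicates biological. For leaves and root tips no label says whether replicates came from separate plants, so p-values there measure only the spread between these samples, which may be technical.

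The deposited values are intensity values on a linear scale, 1 Affymetrix signal per probe set and array. Signals were made with the Affymetrix software GCOS, per the submitters' processing notes. The version of GCOS, its scaling target and its detection calls are not given in the sources used here. From the values themselves, every array had the same trimmed mean of 500 after the highest and lowest 2% of signals were left out, so the deposited table already carried a global scaling between arrays, and that scaling was kept. Signals ranged from 0.0268 to 17262. Such a scaling assumes that the trimmed mean signal of an array is equal between samples. A change in many bright transcripts that are not trimmed would shift all others slightly, which is why other scalings were run as alternatives.

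From these signals, values under a floor of 50, which is 10% of the trimmed mean, were set to the floor, and log2 was taken. The fold change of a dim probe set therefore depends on the floor. It is a lower bound only where the group at the floor is the dimmer one and the other group's arrays lie above the floor. A probe set was tested in a tissue when it exceeded the floor on at least 4 fruit arrays, 3 leaf arrays or 3 root tip arrays. Of the 10209 probe sets in the table, 108 housekeeping and hybridisation controls and 63 reporter controls stayed out of the tests. The share of probe sets above the floor lay between 54.7% and 63.8% per array. The number of arrays limits the precision of every value.

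Differences were tested with limma 3.58.1 in R 4.3.3, in a separate fit for each tissue with a mean per genotype, a variance trend and no covariate. All adjusted p-values are two-sided moderated tests from limma with Benjamini-Hochberg adjustment over all probe sets tested in that tissue, and a probe set was called at an adjusted p under 0.05. The leading comparison set the mean of N6 and N7 against the mean of wild type and vector control. Its spread is that between arrays of a genotype, so variation between independently transformed lines is not in the p. The count is therefore given beside those of the 2 other pairings of the 4 genotypes. Pairwise contrasts of each line with the vector control, of the vector control with wild type and of the lines with each other came from the same fits. Differences between tissues were tested as contrasts of the effects, on probe sets kept in both tissues. Concordance of the lines was measured as a correlation across probe sets, which are not independent replicates, with each line set against a different control group so that no array was shared.

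Gene symbols came from the platform's annotation. It gave 1 symbol to 909 probe sets, none to 9129 and several to 0. Through the gene identifier, 885 of the 909 were matched to a gene table of the tomato assembly SLM_r2.1, which was used for names only, and 24 kept the name of the annotation. The symbols covered 803 genes. Probe sets with no symbol here are counted in the tests but carry no name in the text. Genes were named in the text by a fixed rule: per tissue, among called probe sets with an informative symbol and with both lines on the same side of both controls, the 10 with the highest and the 10 with the lowest log2 difference, with 1 probe set per gene, the brightest. From each described list up to 4 members were added, the 2 with the smallest p that rose and the 2 that fell. Genes named outside this rule are introduced as chosen after their values were seen.

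The comparisons, the tests, the naming rule, 22 gene lists and the alternative settings were fixed before the data were examined. Because most symbols on the array are old gene names, many of the 22 lists had too few measured members, and 30 further lists were written from the symbols on the array, before any difference per gene was looked at. Lists of at least 5 measured genes were tested with camera of limma at a preset correlation of 0.01, with 1 probe set per gene and all other symbol genes as the background, and adjusted over the lists of a kind and tissue. Each test was repeated with a correlation estimated for the list. The level of a list's change "adjusted over the list alone" counts members called when only the list's members are adjusted for. RNA quality was described by the log2 ratio of the 3' to the 5' probe set of the control genes for actin, GAPDH, EF1A and ubiquitin, as the mean of the 4, and compared between lines and controls by an exact permutation test.

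The test of lines against controls and the list test were tried on simulated data of each tissue. Independent normal noise with the estimated variance of each probe set was added to its control mean. For the first test 200 probe sets were changed by known folds. Pairwise contrasts and differences between tissues were not simulated. Neither outlying arrays nor correlation between genes was simulated, so the false calls below may understate those in real data. In the fruit comparison (6208 probe sets) 86.6% of 2-fold changes and 47.8% of 1.5-fold changes were recovered, with 11 false calls. For leaf (6534 probe sets) these values were 83.6%, 53.7% and 6, and for root tips (6495 probe sets) 74.6%, 49.3% and 6. A simulated list shift was recovered in each of the 3 tissues, with 0, 0 and 1 of 19 other lists called.

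Settings fixed beforehand as alternatives were quantile and median scaling, no floor, a doubled floor, no filter and a stricter filter on dim probe sets (mean log2 signal 1 above the floor), no variance trend, the replicate number as a block, each control group alone, a fit over all tissues together, the mean over a gene's probe sets, an estimated list correlation, and leaving out each array in turn. Chosen after seeing the data were fits without fruit wild type 3 and vector control 4, with array weights, with the 3'/5' ratio as a covariate, and a fruit comparison of N7 with vector control 1 to 3 alone. Their effect on the counts of calls is given in the closing section. No array was left out of the reported fits.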

Results

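Transcripts were profiled in tomato (Solanum lycopersicum, the dwarf cultivar Micro-Tom) to compare 2 transgenic lines, N6 and N7, with wild type (WT) and a vector control (VC). Both lines carry a gene for an inositol polyphosphate 5-phosphatase (InsP 5-ptase), an enzyme that removes a phosphate from inositol phosphates, among them the messenger that releases calcium inside cells. Ripe fruit came from pot-grown plants and gave 16 arrays, 4 per genotype. Leaves of young light-grown seedlings and root tips gave 12 arrays each, 3 per genotype. The sample descriptions call the root tip seedlings etiolated, but the growth text for roots repeats that for leaves, in light, so their growth conditions are not settled. The design asks which transcripts differ between the lines and the controls in each tissue, and how far the lines and the tissues resemble each other. Arrays of a genotype correlated at 0.93 to 0.996 across probe sets, with no array duplicated. The introduced gene itself was not analysed here.

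Reporter control probe sets, which detect sequences used in plant transformation, gave a check of the labels. Probe set A06498 was above the floor on 16 of the 40 arrays, all of them of the transgenic lines. Its signal was 436.6 ± 191 (SD, n = 3) in leaf N7, 138.9 ± 41.9 (n = 3) in leaf N6, 328.1 ± 108 (n = 3) in root tip N6, 303.1 ± 89.8 (n = 3) in root tip N7 and 278.0 ± 42.4 (n = 4) in fruit N7. The fruit arrays labelled N6 gave 12.2 ± 8.22 (n = 4), near the 16.7 ± 6.60 of fruit labelled WT. Probe set M62653, whose name is that of a green fluorescent protein sequence, was at 2513 ± 1357 (n = 4) in fruit labelled WT and at 5161 on the fruit array labelled VC replicate 4. On the other fruit arrays labelled VC it was at most 10.1. In fruit labelled N6 it was 0.272, 51.0, 20.2 and 38.6 on replicates 1 to 4, with N6 2 just above the floor. In fruit labelled N7 it was 7.38 to 9.11. On every leaf and root tip array it was under the floor of 50. What the A06498 sequence is was not given in the sources used here, so it was read only by comparing groups. M62653 is at odds with the labels of fruit WT and VC 4, and A06498 in fruit labelled N6 differs from leaf and root tip N6. All fruit values below are of libraries as labelled. The reporter plot gives both probe sets and EIN2 on each array.

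**Figure D1:**
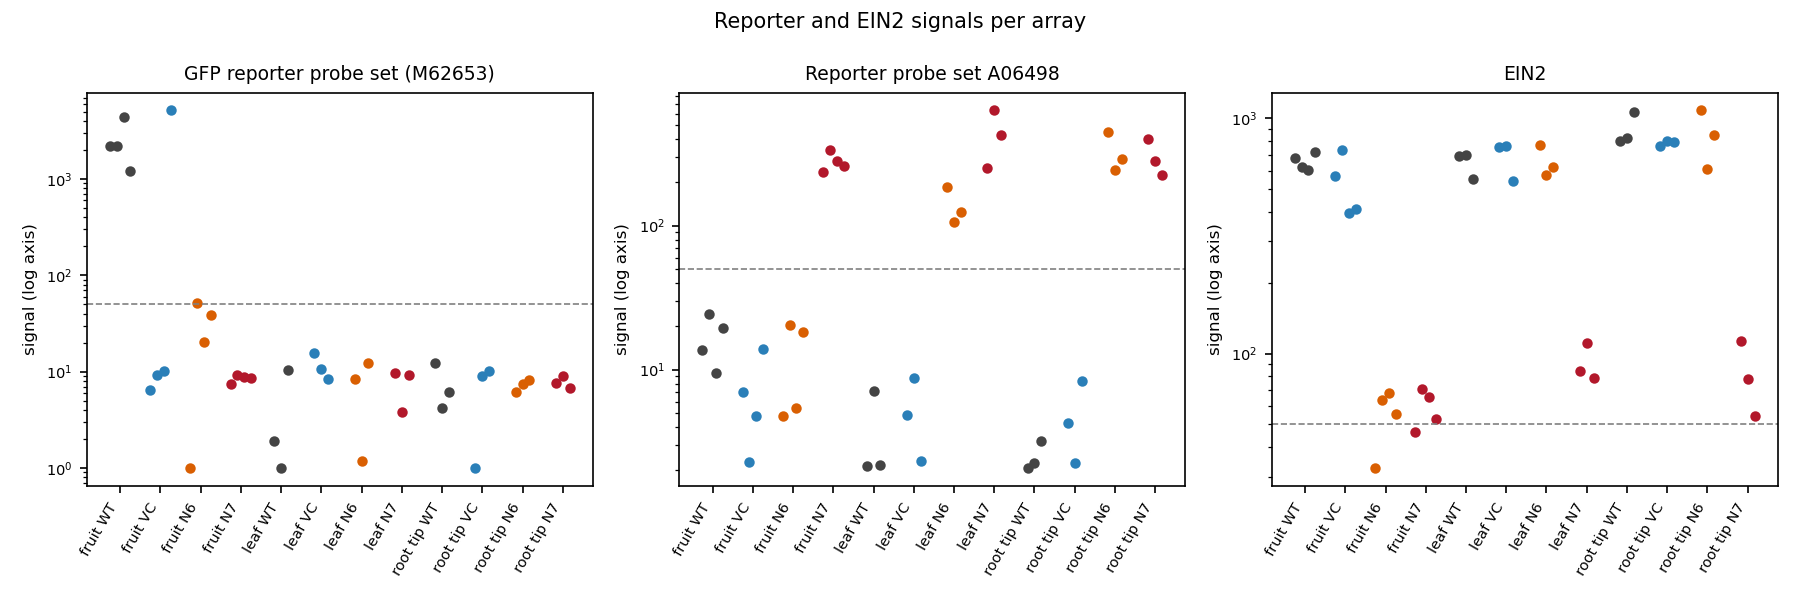
Signal (log axis) of reporter probe sets M62653 and A06498 and of EIN2 on each of the 40 arrays, by tissue and genotype label; each dot is an array, the dashed line is the floor of 50, and signals under 1 are drawn at 1. M62653 is high in fruit labelled WT and VC 4, A06498 is high in the lines except fruit labelled N6, and EIN2 is low in N7 of all 3 tissues and in fruit labelled N6.

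In ripe fruit, the libraries labelled N6 and N7 carried more transcript of CIF1, an inhibitor of invertase, and less of lin5, a cell wall invertase, than the libraries labelled WT and VC. CIF1 rose 6.39-fold (log2 difference 2.68 ± 0.14 SE, 8 against 8 arrays, adjusted p = 9.85e-10), and lin5 fell to the floor in both lines, at least 5.61-fold (-2.49 ± 0.18, adjusted p = 3.95e-08). Among genes with a symbol, TGAS118 had the highest increase, 12.4-fold (3.63 ± 0.26, adjusted p = 4.55e-08). Among the same genes and with all fruit arrays, the lipid transfer protein gene TSW12 had the deepest decrease. It was at least 10.5-fold, with N7 3 under the floor (-3.39 ± 0.54, adjusted p = 1.81e-04). Against VC alone, TSW12 fell in N7 (-3.89, adjusted p = 0.00199) and was not called in N6 (-1.77, adjusted p = 0.121). EIN2, a membrane protein through which the ethylene signal passes, fell at least 9.78-fold, since arrays N6 1 and N7 1 were under the floor (-3.29 ± 0.15, adjusted p = 2.83e-10). The rank of TSW12 rested on VC 4. Without that array TSW12 was at -2.9, while EIN2 lay between -3.35 and -3.2 with each array left out in turn. The small heat shock protein HSP17.4 fell 8.89-fold (-3.15 ± 0.24, adjusted p = 7.31e-08) and PSBP, of the oxygen-evolving complex of photosystem II, 7.47-fold (-2.90 ± 0.17, adjusted p = 2.92e-09).

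Other genes that rose in fruit of the lines were SIP (log2 difference 2.16), the lipoxygenases LOX1.1 (2.06) and TomloxE (1.07), the lipid transfer protein LE16 (1.91), the metal transporter Nramp2 (1.77), ats1 (1.70), TDR8 (1.35) and the cap-binding translation factor eIF4E1 (1.14). Others that fell were the dehydrin TAS14 (-3.15), the phosphate starvation gene TPSI1 (-3.03), TUB (-2.95), the cold response factor CBF1 (-2.67), the small heat shock protein vis1 (-2.57) and PDH (-2.50). For vis1 the arrays of N6 were all at the floor and the controls above it, so its fold is a lower bound, as are those of TAS14 (N6 1 under the floor) and Nramp2 (WT 4 and VC 2). For CBF1 the arrays of N7 but also control arrays WT 3 and VC 4 were under the floor, so its difference is no bound, and without the floor it was -2.43 and not called (adjusted p = 0.0957). Each of the 20 genes was on the same side of the control mean in 8 of 8 line arrays, which the rule that chose the genes made likely. Single control arrays could still reach the lines, as for SIP, where WT 3 was at 10.27 (log2) and the mean of N7 at 10.24.

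Of 8 fixed gene lists with at least 5 measured members, 0 were called in fruit by camera, with 2 at an unadjusted p under 0.05 and 0 called with an estimated correlation. The ethylene and ripening list had 8 members that rose and 2 that fell of 22 (10 adjusted over the list alone). The transcription factor EIL1 (0.48 ± 0.07) and the receptor ETR2 (0.83 ± 0.12) rose, and EIN2 and the ACC oxidase ACO4 (-1.65 ± 0.15), which makes ethylene, fell. The median of the list was 0.20 and its mean -0.03, and the test (up, adjusted p = 0.18) went with the median. In the sucrose and hexose list 1 of 11 rose and 5 fell (9 over the list alone, adjusted p = 0.159), with SPS, sucrose phosphate synthase, at 0.44 ± 0.08 and sus3, a sucrose synthase, at -0.71 ± 0.07. Among pathogenesis-related proteins 1 of 7 rose and 5 fell (6 over the list alone, adjusted p = 0.292). The chitinases CHI3 (-1.25 ± 0.20) and CHI9 (-1.49 ± 0.30) fell and the osmotin-like NP24-I (0.35 ± 0.12) rose.

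The dehydration and abscisic acid list had 1 member that rose, LE16, and 3 that fell of 5 (4 over the list alone, adjusted p = 0.461), among them TAS14 and ER5 (-2.30 ± 0.36, N6 at the floor). In the wound and jasmonate list LOX1.1 and OPR3 (1.02 ± 0.16) rose and loxD (-1.62 ± 0.26) fell, of 6 (3 over the list alone, adjusted p = 0.461). Of 13 carotenoid and isoprenoid genes 2 fell, DXS (-0.48 ± 0.10) and NSY (-0.97 ± 0.26) (2 over the list alone, adjusted p = 0.579). In the cell wall list 1 of 6 fell, the polygalacturonase PG2 (-1.46 ± 0.18) (3 over the list alone, adjusted p = 0.941), and of 5 antioxidant enzymes APX1 fell (-0.66 ± 0.20) (2 over the list alone, adjusted p = 0.461). Lists for seed, green and vascular cells had 0 members among the symbols of the array.

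Of 28 added lists tested in fruit, 2 were called. In the photosynthesis apparatus 8 of 13 measured genes fell and 1 rose (camera adjusted p = 0.00345), among them PSBP, PSBO (-2.12 ± 0.23), CAB4 (-1.90 ± 0.15) and PsbQ (-1.59 ± 0.20). Of 10 heat shock proteins and chaperones 7 fell (camera adjusted p = 0.00345), among them HSP17.4, vis1, HSP21 (-2.18 ± 0.20) and MTSHP (-1.80 ± 0.14). Neither call held with an estimated correlation (adjusted p = 0.0592 for photosynthesis and adjusted p = 0.283 for heat shock). The mean log2 3'/5' ratio of the control transcripts was 3.42 in fruit of the lines and 3.89 in fruit of the controls (exact permutation p = 0.14).

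In all, 1928 of 6208 probe sets were called in fruit, 1029 higher and 899 lower in the lines (limma), against 39 and 31 in the 2 other pairings of the genotypes. Of the called probe sets 459 differed by over 2-fold, 144 higher and 315 lower. Symbol genes made up 237 of the calls, 96 higher and 141 lower. With median scaling, which moved the median of all probe sets from 0.04 to 0.10, the share of higher calls was 66% in place of 53.4%. Arrays WT 3 and VC 4 stood apart from the other fruit controls; without them 3294 probe sets were called (1971 higher), and photosynthesis (adjusted p = 0.00737) and heat shock (adjusted p = 0.00788) were called again, neither of them with an estimated correlation (adjusted p = 0.0655 and 0.384). A comparison of N7 with VC 1 to 3 alone, the fruit libraries with no reporter signal at odds with their labels, called 2361 of 5661 probe sets (1502 higher). In VC 1 to 3 no reporter probe set was above the floor, so no signal tells them from untransformed fruit. Its 7 arrays are also part of the fit of all fruit arrays, which called 1353 of the 2361.

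Between the fruit lines and the vector control taken singly, 1087 probe sets were called for N6 (553 higher) and 1370 for N7 (801 higher). CIF1 rose in both (2.27 in N6 and 2.71 in N7) and PSBP fell in both (-3.39 and -2.62). Fold changes of the lines, each against a different control, correlated at 0.752 across probe sets, and the pairing without a transgene contrast at -0.058. The lines differed from each other in 180 probe sets, 120 of them higher in N7, a share of 66.7% that was 48.4% with median scaling, where 95 were called. Among them HSP17.4 was higher in N7 than in N6 by 1.78 (adjusted p = 0.00626), while EIN2 was too near the floor in both lines (means of 55.1 and 58.8) for a difference to be read. Against the vector control, N6 gave 687 without VC 1 and 1684 without VC 4, and N7 gave 908 without VC 3 and 2070 without VC 4. N7 against N6 gave 83 without N6 3, 94 without N6 2, 95 without N7 4, 96 without N7 2 and 106 without N7 1, but 285 without VC 4 and 286 without WT 3. The vector control and wild type differed in 0 probe sets by limma, with 331 at an unadjusted p under 0.05, 10 called without VC 4 and 1 without VC 2. Array weights gave 1316 in place of 0, and leaving out both WT 3 and VC 4 gave 21, so that the 0 depended on how these arrays were treated.

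In leaves of the transgenic lines, the ethylene receptor ETR4 rose 8.51-fold (3.09 ± 0.24 SE, 6 against 6 arrays, adjusted p = 2.09e-05) and the ethylene response factor erf1a at least 7.65-fold, with control arrays WT 2, VC 1 and VC 2 under the floor (2.94 ± 0.33, adjusted p = 2.13e-04). ERF3 rose at least 5.70-fold, since all control arrays were at the floor (2.51 ± 0.34, adjusted p = 6.35e-04). The thaumatin-like defence proteins NP24-I and PR5 rose 5.64-fold (2.50 ± 0.41, adjusted p = 0.00178) and 5.32-fold (2.41 ± 0.33, adjusted p = 6.77e-04). CIF1 rose 5.56-fold in leaf as well (2.47 ± 0.19, adjusted p = 2.27e-05).

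Others that rose in leaf were GluB, a glucanase (log2 difference 2.22), the xyloglucan endotransglucosylases tXET-B2 (2.05, controls at the floor) and XTH3 (2.05, VC at the floor), and IAA17 (1.98), an auxin response repressor. Against VC, tXET-B2 was called in N6 (2.95, adjusted p = 0.00332) and not in N7 (1.16, adjusted p = 0.178). It was above the control mean in 5 of 6 line arrays. The 10 named genes that fell did so by less. PTOX, a plastid oxidase, fell at least 2.99-fold with N6 at the floor (-1.58 ± 0.22, adjusted p = 6.75e-04), and the glutathione peroxidase GPXle-2 2.88-fold (-1.53 ± 0.20, adjusted p = 5.00e-04). VPE5, a vacuolar processing enzyme, was at -1.52, the remorin rem-1 at -1.34, AOC, an allene oxide cyclase of jasmonate synthesis, at -1.21 and ST3 at -1.20. ARPI, with arrays of lines and controls under the floor, and Xegip, an inhibitor of xyloglucan endoglucanase, were both at -1.09, TAO2 at -1.07 and the hexokinase hxk1 at -1.06. For ARPI the mean log2 signal of WT (6.02) was near those of N6 (5.86) and N7 (5.94). Only VC was higher (7.97), so its difference came mainly from VC, though VC against WT was not called (1.96, adjusted p = 0.425). Without the filter on dim probe sets GluB (adjusted p = 0.0905) and ARPI (adjusted p = 0.0982) were not called. With the floor doubled ARPI was at -0.68 and not called (adjusted p = 0.0522). With the 3'/5' ratio as a covariate, GluB (1.97, adjusted p = 0.15) and ARPI (-0.66, adjusted p = 0.281) were not called, and both calls also depended on single arrays. GluB was lost without each of 4 arrays (WT 1, N6 1, N7 1 or N7 2; adjusted p = 0.0525 to 0.0571), and ARPI without each of 7 (WT 1, VC 1, VC 2, N6 2, N6 3, N7 1 or N7 2; adjusted p = 0.0649 to 0.0735).

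Of 7 fixed lists tested in leaf, 2 were called. In the ethylene and ripening list 7 of 14 measured genes rose and 2 fell (11 adjusted over the list alone; camera adjusted p = 0.0114, up). The receptors ETR4 and ETR5 (1.35 ± 0.14) rose, and EIN2 (-1.45 ± 0.14) and the receptor ETR2 (-0.75 ± 0.11) fell. Of 5 pathogenesis-related proteins 2 rose, PR5 and NP24-I (3 over the list alone; camera adjusted p = 0.0128, up). With an estimated correlation the adjusted p was 0.404 for either list, and the second was not called without the filter on dim probe sets (adjusted p = 0.106). Leaf controls had a mean log2 3'/5' ratio of 4.82 and the lines 4.44 (exact permutation p = 0.0498, adjusted over the 3 tissues p = 0.149). RNA quality may thus have differed between the groups in which these lists were compared, though not past the threshold after adjustment.

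Other fixed lists in leaf gave 2 genes up and 2 down of 13 for carotenoids (5 over the list alone, adjusted p = 0.512), with CrtR-b1 (1.76 ± 0.26) and Psy1 (1.05 ± 0.20), a phytoene synthase, higher and PDS, phytoene desaturase (-0.54 ± 0.11), and VDE (-0.86 ± 0.23) lower. In the sucrose and hexose list 3 of 13 fell (3 over the list alone, adjusted p = 0.306), among them hxk1 and LIN8 (-0.97 ± 0.22). In the wound and jasmonate list loxC rose (1.68 ± 0.42) and AOC fell, of 7 (3 over the list alone, adjusted p = 0.327). Of 5 antioxidant enzymes APX1 fell (-0.62 ± 0.14) (1 over the list alone, adjusted p = 0.249), and of 5 dehydration genes 0 passed the test (0 over the list alone, adjusted p = 0.327 by camera of limma, with 0 called). Of 28 added lists, that of ERF and DREB transcription factors was called (camera adjusted p = 3.90e-04, up): 10 of 12 rose, among them erf1a, ERF3, DREB3 (1.11 ± 0.19) and ERF2 (1.23 ± 0.23), and DREB1 fell (-0.89 ± 0.20). With an estimated correlation its p was 0.056 (adjusted p = 0.741).

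In leaf 1200 of 6534 probe sets were called, 639 higher and 561 lower in the lines (limma), against 23 and 74 in the other pairings. Of these, 155 were symbol genes, 88 higher and 67 lower. With the 3'/5' ratio as a covariate 593 were called, and without VC replicate 1 the count was 794. With array weights, whose fit stopped before convergence, it was 2694, and without N7 replicate 3 it was 1556. No filter gave 874. Each control alone gave 659 (VC) and 788 (WT). Median scaling moved the share of higher calls from 53.2% to 39.7%.

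Taken singly against the leaf vector control, N6 differed in 692 probe sets (349 higher) and N7 in 462 (252 higher), and the lines differed from each other in 293 (183 higher in N7). ETR4 rose in both, by 3.60 in N6 and 2.64 in N7, and ERF3 rose in N6 by 3.70 (adjusted p = 8.55e-04) and was at 1.32 in N7 (adjusted p = 0.12), a difference between the lines of -2.38 (adjusted p = 0.0201). EIN2 fell in N7 (-2.91, adjusted p = 1.49e-05) and was at -0.06 in N6 (adjusted p = 0.891), and the lines differed by -2.85 (adjusted p = 1.12e-05). The lines' fold changes correlated at 0.466, against -0.237 for the pairing without a transgene contrast. Single arrays moved these counts. N6 gave 258 without VC 1, 320 without VC 2, 336 without N6 2, 358 without N6 3 and 421 without N6 1. N7 gave 118 without N7 2, 122 without VC 1, 129 without VC 2, 248 without N7 1 and 964 without N7 3. N7 against N6 gave 69 without N6 2, 94 without N7 2, 131 without N6 3, 160 without VC 1, 178 without VC 2, 183 without N6 1 and 191 without WT 3, but 709 without WT 2. The vector control and wild type differed in 1 probe set, without a gene symbol (2.32, adjusted p = 0.0281), which was chosen after its value was seen; 0 were called by limma (294 at an unadjusted p under 0.05 with all arrays) without any 1 of the arrays of WT, VC and N7, and 4 without N6 2.

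**Figure D2:**
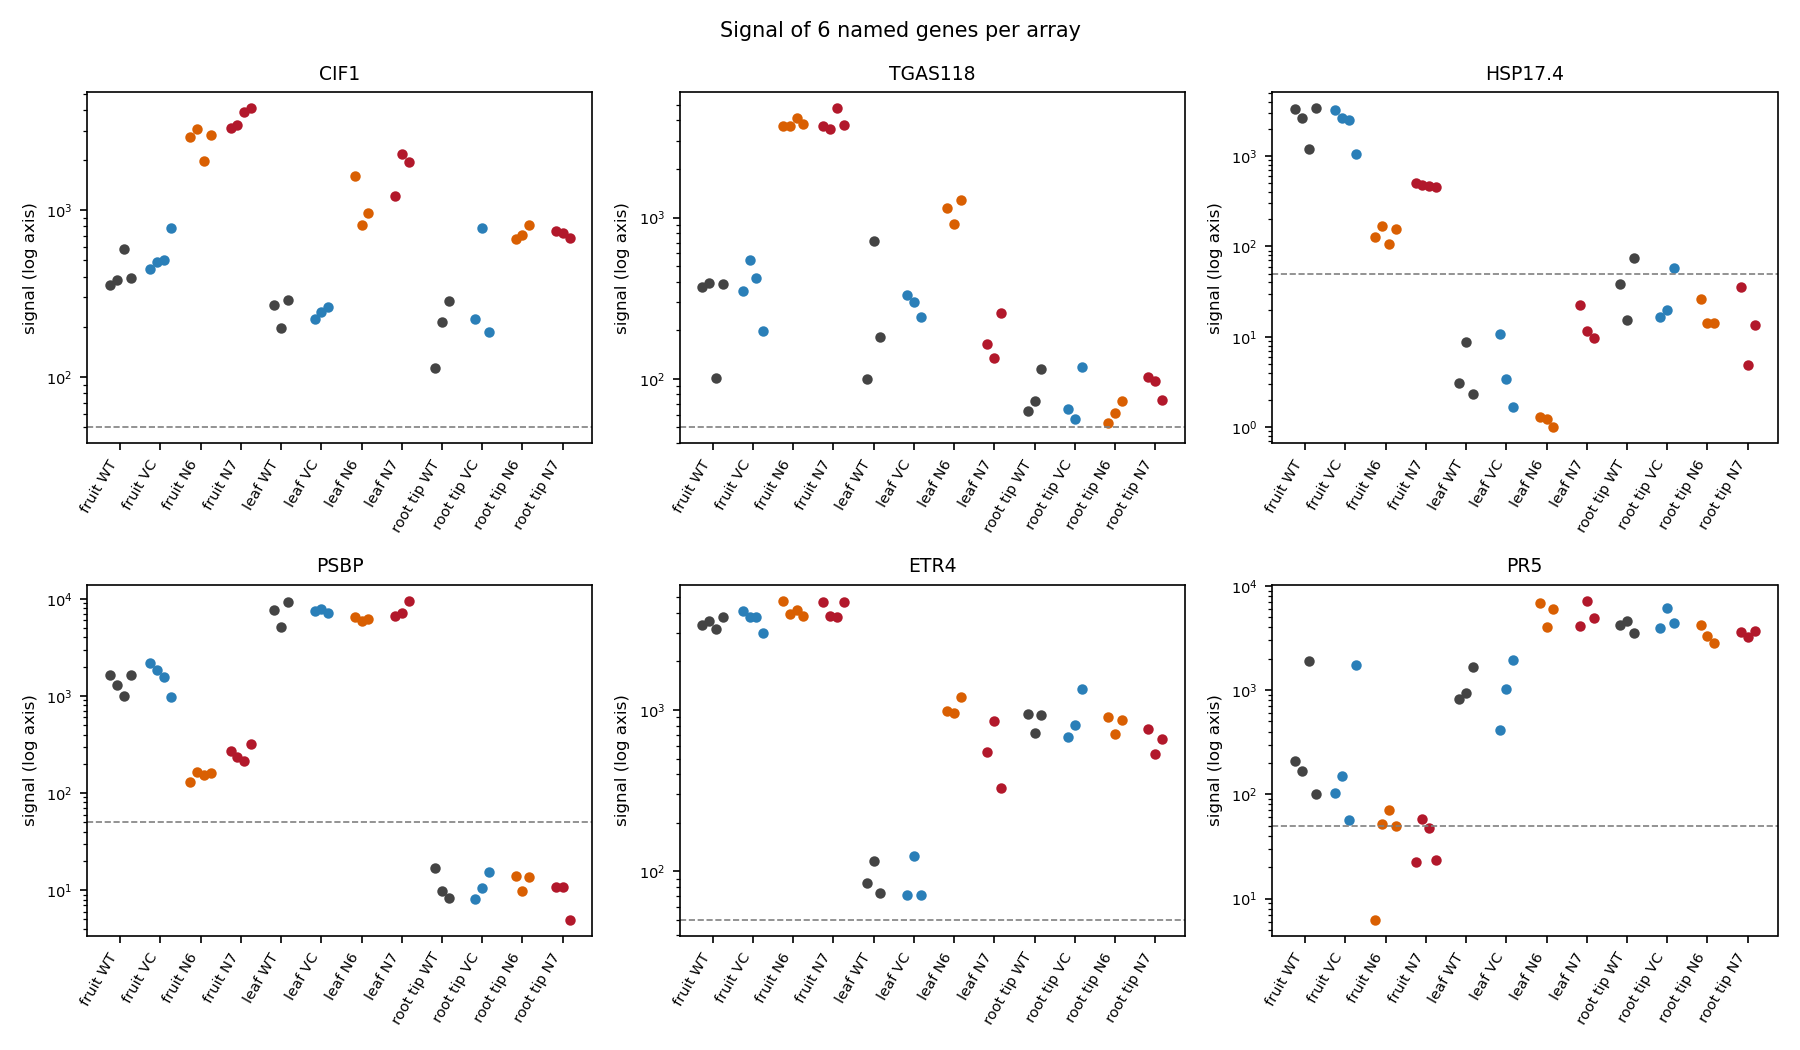
Signal (log axis) of CIF1, TGAS118, HSP17.4, PSBP, ETR4 and PR5 on each array, by tissue and genotype label; each dot is an array, the dashed line is the floor of 50, and signals under 1 are drawn at 1. CIF1 is higher in both lines in fruit and leaf (log2 differences 2.68 and 2.47), ETR4 rises in leaf (3.09), and PSBP falls in fruit (-2.90).

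In root tips of the lines, EIN2 fell 3.30-fold on average (-1.72 ± 0.19 SE, 6 against 6 arrays, adjusted p = 0.00251), and this came from N7, where it fell by 3.33 against the vector control (adjusted p = 1.00e-04) and by 3.40 against N6 (adjusted p = 1.58e-04). ODD fell 3.05-fold (-1.61 ± 0.27, adjusted p = 0.0222), Mdip1 2.55-fold (-1.35 ± 0.25, adjusted p = 0.0325) and the expansin exp9 2.24-fold (-1.16 ± 0.22, adjusted p = 0.0362). Mdip1 was under the control mean in 5 of 6 line arrays. Against VC it was called in N7 (-2.08, adjusted p = 0.0399) and not in N6 (-0.91, adjusted p = 0.498). LysRS, a lysyl-tRNA synthetase, fell by 0.94, DDTFR8 by 0.76 and the sulfate transporter ST1 by 0.65, and the translation factor eIF-5A3 rose by 0.41 ± 0.08 (adjusted p = 0.0362). CIF1 was at 1.55 ± 0.33 and did not pass the test (adjusted p = 0.0629).

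Of 6 fixed lists tested in root tips, the ethylene and ripening list was called (camera adjusted p = 0.00583, down). Of its 18 measured genes 1 fell, EIN2, and 0 rose (4 adjusted over the list alone), its median was -0.23, and with an estimated correlation the p was 0.153 (adjusted p = 0.569). The call was lost with quantile normalization (adjusted p = 0.0543) and without VC replicate 3 (adjusted p = 0.0995). In the other 5 lists limma called 0 members. Their camera adjusted p was 0.854 for 12 carotenoid genes (0 over the list alone), 0.205 for 13 sucrose and hexose genes (1 over the list alone) and 0.205 for 5 phosphate starvation genes (0 over the list alone). It was 0.449 for 7 pathogenesis-related proteins (0 over the list alone) and 0.854 for 5 antioxidant enzymes (0 over the list alone), whose median was -0.03 while mean and test were up. Of 28 added lists, ribosomal proteins and translation factors (up, 1 of 13 rose and 1 fell) and mineral nutrient transport (down, 1 of 13 fell) were called, each at a camera adjusted p of 0.0105. With an estimated correlation the adjusted p was 0.348 and 0.288. Both calls were lost with median scaling (adjusted p = 0.0659 each), and that of ribosomal proteins also without VC 1 (adjusted p = 0.0554) and without N6 1 (adjusted p = 0.0751).

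In root tips 33 of 6495 probe sets were called, 7 higher and 26 lower in the lines (limma), with 845 at an unadjusted p under 0.05, against 2 and 2 in the other pairings. This count depended on the processing: it was 1831 with array weights, whose fit stopped before convergence, 213 with all tissues in a single fit, 151 with the 3'/5' ratio as a covariate, 5 with no filter, 4 with VC alone and 8 with WT alone as the control. It was 18 without N6 2, 20 without N7 2, 21 without VC 3 or N6 1, 51 without N7 3 and 140 without N6 3. Leaving out 1 of the 12 arrays at a time ended the calls of ODD and ST1 in 6 cases each, exp9 in 8, eIF-5A3, LysRS and DDTFR8 in 9 each and Mdip1 in 10. No filter ended those of eIF-5A3, ODD, Mdip1, exp9, LysRS and ST1 (adjusted p = 0.0767 to 0.15). Median scaling ended those of eIF-5A3, LysRS, DDTFR8 and ST1 (adjusted p = 0.0536 to 0.104). The call of eIF-5A3 was also lost with quantile normalization and without the variance trend, and that of LysRS with no floor. The mean log2 3'/5' ratio was 2.97 in the lines and 2.85 in the controls (exact permutation p = 0.656). N6 differed from the vector control in 0 probe sets by limma (562 at an unadjusted p under 0.05) and 1 without N6 3, N7 in 10 (4 higher; 5 without any 1 of the WT and VC arrays, 6 without N7 1 or N7 2 and 22 without N6 2), and the vector control from wild type in 0 (60 at an unadjusted p under 0.05). The lines differed from each other in 3, all lower in N7: EIN2 and 2 probe sets without a gene symbol (-4.12 and -1.38), chosen after their values were seen. Without WT 3 or VC 3 there were 5, and without N6 2 there were 9. The lines' fold changes correlated at 0.412, against -0.072 for the pairing without a transgene contrast.

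**Figure D3:**
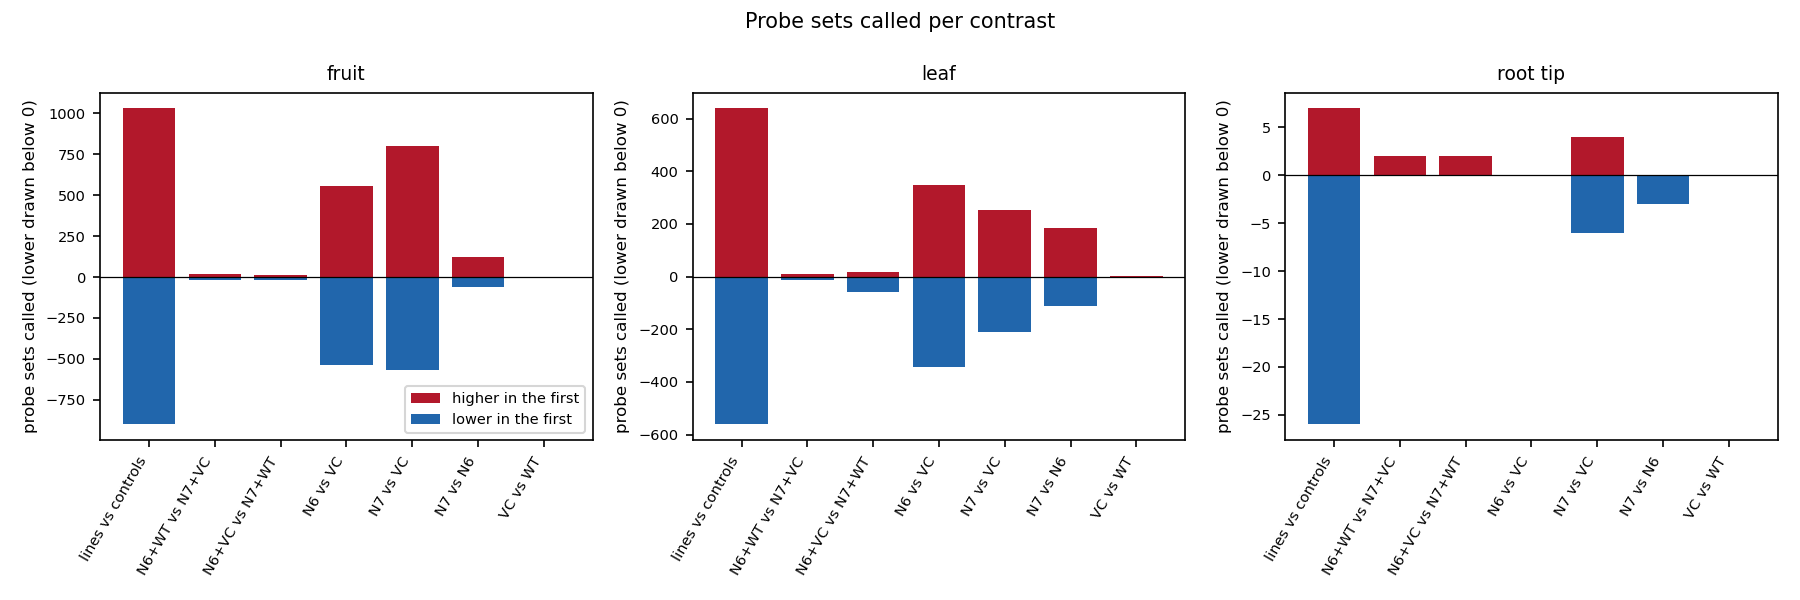
Probe sets called (limma, adjusted p under 0.05) per contrast in each tissue, with those higher in the first-named group drawn above 0 and those lower drawn below; each panel has its own axis. The contrast of lines with controls calls 1928 in fruit, 1200 in leaf and 33 in root tips, and the other pairings of the 4 genotypes call 39 and 31, 23 and 74, and 2 and 2.

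Across tissues, CIF1 rose in both fruit and leaf, and the difference between them did not pass the test (-0.20, adjusted p = 0.583), while PR5 rose in leaf and fell in fruit (-2.15 ± 0.63), a difference of 4.56 (adjusted p = 1.44e-04). PR5 signals in the fruit controls were 1880 on WT 3 and 1738 on VC 4 and at most 209.3 on the other 6 arrays, so the size of its fall in fruit rested on those arrays. The xyloglucan endotransglucosylases tXET-B2 and XTH3 also rose in leaf and fell in fruit, where they were at -1.94 (both lines at the floor) and -1.78, with differences of 3.99 (adjusted p = 9.07e-06) and 3.83 (adjusted p = 4.14e-06). Against VC, the leaf rise of tXET-B2 was called in N6 and not in N7. PSBP fell in fruit and was at -0.09 in leaf, a difference of 2.81 (adjusted p = 1.01e-09). Xegip fell in fruit (-1.12 ± 0.13) as in leaf, with a difference of 0.03 that did not pass the test (adjusted p = 0.91). Of 5596 probe sets tested in leaf and fruit, 93 were called higher in both (93.2 by independent lists) and 84 lower in both (68.2). Another 88 were higher in leaf and lower in fruit (81.2), and 110 lower in leaf and higher in fruit (78.3). Effects in leaf and fruit correlated at -0.017 across probe sets, and the difference was called for 1477. Root tips shared 5 higher and 8 lower calls with fruit (1.2 and 1.9 by independent lists) and 4 and 9 with leaf (0.7 and 1.5), with differences called for 1010 and 666 probe sets.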

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

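All tests of the reporter signal and of EIN2 in this part were chosen after the result was seen; the tests of fruit WT 3 and VC 4 were written before their outcome was known.

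Single arrays lay far from the other 3 of their group for 11 of 86 groups of 4 fruit arrays tested. A chance rate of about 1 in 20 is no fair measure here. Genes share the same arrays, so the groups are not independent, and in some groups the other arrays were all at the floor. On the log2 scale, the array labelled WT 3 was at 6.65 for TGAS118 (others 8.54 to 8.62), 10.27 for SIP (7.96 to 8.21), 11.81 for TAS14 (9.94 to 10.19), 9.65 for TPSI1 (others up to 11.27) and 5.64, the floor, for CBF1 (8.63 to 9.22). The array labelled VC 4 had 61.3% of probe sets above the floor (others 54.7 to 55.8). Among the lines, N7 3 was at 12.21 for TGAS118 (11.79 to 11.86), N6 1 at 11.71 for LOX1.1 (10.57 to 10.68) and N7 4 at 10.23 for LE16 (10.86 to 10.92). Where the other arrays were at the floor of 5.64, N6 4 was at 6.02 for CBF1 and N7 4 at 6.48 for vis1.

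At least 1 test of a difference in effect between tissues was passed by 38 of 41 named probe sets. Each was tested for every pair of tissues that kept it. These genes were named for a strong effect in 1 tissue, which favours such a difference, and the share is no measure of how often effects differ. Over all probe sets, 1477 of 5596 passed for leaf minus fruit, 1010 of 5535 for root tip minus fruit and 666 of 5740 for root tip minus leaf. These are shares of a single comparison and not comparable with 38 of 41. Below, 1 difference is given per gene, though others may have been tested. Leaf minus fruit was 3.99 for tXET-B2, 3.87 for CBF1, 3.83 for XTH3, 3.40 for TSW12, 3.24 for ERF3, 3.23 for vis1, 2.85 for ETR4, 2.81 for PSBP, 2.81 for TPSI1, 2.60 for DDTFR8, 2.14 for NP24-I and 1.84 for EIN2. It was -1.10 for TAO2, -1.12 for AOC, -1.28 for eIF4E1, -1.42 for TomloxE, -1.50 for ST3, -1.93 for PTOX, -2.05 for GPXle-2, -2.07 for VPE5, -2.31 for LE16, and -2.34 for both Nramp2 and SIP. Some leaf effects came from a single line. In leaf, CBF1 was above the floor only in N6 and vis1 only in N7. Leaf Nramp2 was low only in N6 (mean log2 5.95, against 7.92 in N7). The fruit difference of CBF1 is no bound, as given above. Root tip minus fruit was 3.64 for TAS14, 3.19 for PDH, 3.11 for TUB, 0.98 for Xegip, -0.93 for exp9, -1.12 for CIF1, -1.67 for ats1, -2.45 for LOX1.1 and -3.70 for TGAS118. Root tip minus leaf was 1.25 for rem-1, 0.85 for hxk1, 0.63 for eIF-5A3, -2.74 for GluB, -2.76 for PR5 and -3.54 for erf1a.

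Reporter probe sets, which no comparison used, gave signals above the floor in fruit controls and in the lines. In fruit labelled WT the mean signal was 2513 for M62653 (1198 to 4416) and 2343 for AF292560 (909 to 5047), and on the array labelled VC 4 they were at 5161 and 5216. For A06498 the means were 278.0 in fruit N7, 138.9 in leaf N6, 436.6 in leaf N7, 328.1 in root tip N6 and 303.1 in root tip N7. An exchange of all labels between fruit WT and VC, as the only cause, is argued against by the count of fruit control libraries above the floor for M62653, 5, where a group has 4. An exchange with 1 further library misplaced or mixed stays open. Cross-hybridisation of a transcript common to ripe fruit is argued against by VC 1 to 3, whose highest signal was 10.1. RNA of a plant that carries the reporter, in place of or mixed into these libraries, stays open, since 0 leaf and root tip libraries were above the floor and no label names such a plant. No biological explanation was tested.

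EIN2 and 2 probe sets without a gene symbol were low in N7 of each tissue, but in N6 only in fruit. Of the unnamed probe sets, 1 was also low in fruit WT 3 (455.3) and VC 4 (413.6), against 2635 to 3573 in the other 6 fruit controls and 62.0 to 126 in the fruit lines, so its low signal was not confined to the lines. Mean EIN2 signals were 55.1 in fruit N6 and 58.8 in fruit N7, 656 in leaf N6 and 91.2 in leaf N7, and 846 in root tip N6 and 81.6 in root tip N7. That the fruit libraries labelled N6 hold RNA of N7 as analysed in the other samples is argued against by A06498, whose highest signal in them was 20.3, under the floor of 50, while the fruit libraries labelled N7 had 237 to 336. What sequence A06498 is was not given in the sources used here. An effect of the transgene in N6 that differs between tissues stays open, with EIN2 at -0.06 against VC in leaf N6, because fruit from other plants than the label says could give the same values.

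Fruit WT 3 and VC 4 stood apart from the other fruit controls, and their deviations correlated at 0.828 across probe sets, which are not independent replicates. Among the fruit controls they had the lowest mean log2 3'/5' ratios (2.67 and 2.96, others 3.53 to 4.70), the highest M62653 (4416 and 5161, other WT 1198 to 2223) and AF292560 (5047 and 5216), and the low signal of the unnamed probe set given above. The first 2 principal components of the fruit arrays held 45.1% and 24.7% of the variance. RNA quality may have a part: their deviations correlated at 0.478 and 0.324 with the effect of a lower 3'/5' ratio, estimated from the other 14 fruit arrays, between the bounds set for and against. Another ripening stage cannot be told apart from these values either, as the median deviation of the ripening list was -0.02 in WT 3 and -0.36 in VC 4, and that of the photosynthesis list -0.22 and -0.01.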

How the results depend on the processing

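Chosen after the results were seen were the fits without fruit WT 3 and VC 4, with array weights, with the 3'/5' ratio as a covariate and of fruit N7 against VC 1 to 3 alone, and the estimated list correlation in the first and last of these; the other settings were fixed beforehand. Across those fixed settings, the calls of named genes kept direction and side of the threshold in 479 fruit, 385 leaf and 68 root tip cases and fell under it in 1, 14 and 72, and under added ones in 79, 38 and 14 cases against 0, 2 and 0. None reversed. For these and the results below the cause was not tested, except that fewer probe sets or arrays were tested where the alternative removes them. Signals near the floor limit the folds of dim genes.

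Calls for lines against controls in fruit, leaf and root tips were 2273, 1296 and 45 with quantile normalization, 1934, 1206 and 27 with median scaling, and 1905, 1195 and 35 without the variance trend. They were 2056, 1256 and 37 with no floor, 1716, 1037 and 32 with the floor doubled, and 1686, 1011 and 39 with the stricter filter. No filter gave 1626 in fruit and 874 in leaf, and all tissues in one fit 2275 and 1314. VC alone as the control gave 1474 in fruit and WT alone 1347, the covariate 2336, and N7 against VC 1 to 3 alone 2361. With the mean over a gene's probe sets 0, 2 and 1 fixed lists were called, as in the reported fits. With median scaling, fruit N7 against N6 gave 95 calls (46 higher). Without fruit WT 3 and VC 4 the counts were 3294 for lines against controls, 2392 for N6 and 2816 for N7 against VC, 21 for VC against WT, 717 for N7 against N6 and 1955 for root tip minus fruit, and the lines' correlation was 0.795. Array weights gave in the same order 4082, 3491, 3792, 1316 and 1912 in fruit. In leaf they gave 2694, 2259, 1505 and 235 for the first 4 of these, with a correlation of 0.559. In root tips they gave 1831, 113 for N6, 353 for N7 and 434 for N7 against N6, with a correlation of 0.532. The weights stopped before convergence in leaf and root tips. With the covariate, fruit N7 against N6 gave 491 and the correlation was 0.715. Leaf gave 593 for lines against controls, 263 for N6 against VC, 0 for VC against WT (limma, 294 at an unadjusted p under 0.05 in the reported fit) and 84 for N7 against N6, with a correlation of 0.542. Root tips gave 151, 18 for N7 against VC and 11 for N7 against N6, with a correlation of 0.35.

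In leaf, VC against WT gave 0 calls by limma with no floor, no filter, the stricter filter and the replicate block, in place of 1. No filter gave 393 for N6, 219 for N7, 91 for N7 against N6 and 1 list called, and the replicate block 195 for N7 against N6. VC alone as the control gave 659 and WT alone 788, and an estimated list correlation 0 lists. In root tips, quantile normalization and an estimated correlation each gave 0 lists in place of 1. N7 against N6 gave 5 with no floor, 5 with the floor doubled and 8 with the stricter filter. No filter gave 5 for lines against controls and 4 for N7 against VC, while VC alone gave 4, WT alone 8, and all tissues in one fit 213.

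Leaving out single arrays gave these ranges. In fruit, lines against controls lay between 1616 (without WT 1) and 2545 (WT 3), N6 against VC between 687 (VC 1) and 1684 (VC 4), N7 against VC between 908 (VC 3) and 2070 (VC 4), VC against WT between 0 and 10 (VC 4), N7 against N6 between 83 (N6 3) and 286 (WT 3), and the correlation between 0.706 and 0.777. In leaf these were 794 (VC 1) to 1556 (N7 3), 258 (VC 1) to 927 (N7 3), 118 (N7 2) to 964 (N7 3), 0 to 4 (N6 2), 69 (N6 2) to 709 (WT 2) and 0.345 to 0.525. In root tips lines against controls gave 18 (N6 2) to 140 (N6 3), N6 against VC 0 to 1 (N6 3), N7 against VC 5 (WT 1) to 22 (N6 2), N7 against N6 2 to 9 (N6 2), lists 0 (VC 3) to 1, and the correlation 0.301 to 0.454. Differences between tissues kept within 1.5 times their counts, at 1330 to 1766 for leaf minus fruit, 814 to 1431 for root tip minus fruit and 450 to 927 for root tip minus leaf. Whether replicate numbers pair arrays was checked on residuals. Arrays with the same number had a median correlation of 0.06 in fruit, -0.01 in leaf and 0.22 in root tips, against 0.02, 0.01 and -0.06 for other numbers. It was over 0.1 in 10 of 24, 5 of 18 and 10 of 18 pairs, and 3 of 16, 2 of 12 and 4 of 12 arrays correlated best with their own number, so the numbers were not taken to pair arrays, with root tips the least clear. As a block the number gave 1780, 1014 and 29 calls for lines against controls. Of the named genes, eIF-5A3 (adjusted p = 0.0547) and DDTFR8 (adjusted p = 0.0557) in root tips were not called with it, and it changed no other call of a named gene or list.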

Other observations

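The genes of the first paragraph were chosen after their values were seen; the regroupings of arrays were planned.

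In fruit of the libraries labelled N6 and N7, genes of amino acid and polyamine metabolism were among the lower ones: adc1 fell (-2.45 ± 0.17), as did GABA-TP3 (-1.92 ± 0.14) and gad2 (-1.70 ± 0.27). Of the 16 measured genes of that added list 8 fell and 2 rose (camera adjusted p = 0.248), and adc1 rose in leaf (1.15 ± 0.19). Among pectin, galactan and mannan hydrolases 4 of 14 fell in fruit and 2 rose (camera adjusted p = 0.656), with LEXYL2 at -1.42 ± 0.18 and TBG3 at 0.66 ± 0.08. ACO6 fell in fruit (-2.08 ± 0.14), and so did GolS-1 (-2.31 ± 0.29). Of 9 xyloglucan endotransglucosylases and endoglucanases 6 fell in fruit (camera adjusted p = 0.246), and without WT 3 and VC 4 the list was called (adjusted p = 0.00737, 8 of 9 fell), but with an estimated correlation it was not (adjusted p = 0.0655, and 0.367 with all fruit arrays). In leaf, 4 of 10 auxin response genes rose and 1 fell (camera adjusted p = 0.322), among them IAA3 (1.92 ± 0.31, WT at the floor), IAA7 (1.35 ± 0.26) and IAA16 (1.11 ± 0.22). Of 8 genes of MAP kinase cascades 4 rose in leaf (camera adjusted p = 0.133), with MPK3 at 1.49 ± 0.27 and MAPKKKalpha at 0.65 ± 0.13. Leaf antioxidant enzymes of the added list had 5 of 22 that fell and 1 that rose (camera adjusted p = 0.0639).

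Arrays were regrouped to ask whether chance between single arrays gives counts as large. Chance differences between lines, or between plants where replicates may be technical, are not covered by this. In fruit, 1 of 100 groupings, the real one, gave as many as the 1928 calls for lines against controls, with 0 in the highest other. The real one alone of 35 did so for N6 against VC (1087, highest other 13) and N7 against VC (1370, highest other 4). The same held for N7 against N6 (180, highest other 7), and chance between single arrays can be excluded for these 4 counts. For VC against WT all 35 groupings had to give at least the real 0 (limma, 331 at an unadjusted p under 0.05), which tested nothing, but 572 were called when WT 1 to 3 with VC 4 were set against WT 4 with VC 1 to 3, which points to a structure of the samples. For the fixed lists the real count in fruit was 0 (camera of limma, 2 at an unadjusted p under 0.05), so that 100 of 100 groupings had to give as many and nothing was tested; the highest gave 4.

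In leaf, 1 of 100 groupings, the real one, gave as many as 1200, so chance between single arrays can be excluded for this count. The highest other, 897, set the 3 N6 arrays with N7 1, WT 2 and VC 3 against the rest. There N7 2 and N7 3 stood with the controls, so a large count did not need the real grouping. Chance between plants or lines is not excluded. For 2 leaf lists called, 29 of 100 groupings gave as many and the highest other gave 4, so chance is not excluded. In root tips 2 of 100 groupings, the real one included, gave at least 33, a share under 0.05. The other gave 428, far above the real count, which points to a structure of the samples. Chance is therefore not taken as excluded for the 33 calls. For the 1 root tip list, 32 of 100 groupings gave as many and the highest other gave 3, so chance is not excluded. Differences between tissues were matched by the real grouping alone of 100. The counts were 1477 for leaf minus fruit (highest other 91), 1010 for root tip minus fruit (6) and 666 for root tip minus leaf (103). These regroupings mixed the genotypes within both tissues, which also removed the effect in each tissue. They asked about no effect in either tissue, not about equal effects in both. Chance is therefore not taken as excluded for these 3 differences between tissues.

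With 3 arrays per group only 10 groupings exist for each pairwise contrast, too few for a share under 0.05. In leaf the real and highest other counts were 692 and 0 for N6 against VC, 462 and 0 for N7 against VC, 1 and 1 for VC against WT, where 2 groupings gave as many, and 293 and 0 for N7 against N6. In root tips they were 0 and 1 for N6 against VC (limma, 562 at an unadjusted p under 0.05), 10 and 0 for N7 against VC, 0 and 0 for VC against WT (60 at an unadjusted p under 0.05) and 3 and 0 for N7 against N6.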
